A study of Homo sapiens with 6 samples.

How the data were processed

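Gene expression was measured on Affymetrix Human Genome U133 Plus 2.0 arrays in 6 samples of OVCA432 cells, 3 that received recombinant human MFAP5 and 3 that received solvent. Per the labels' protocols, total RNA was amplified and labelled with biotin as cRNA, and each sample was prepared independently and put on its own array. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 linear intensity (MAS5 signal) per probe set and array, and MAS5 is the only tool named in the submitters' processing notes, where its version is not given. MAS5 summarises each probe set on each array by itself. The trimmed mean of each column, with 2% left out at each end, was 500.07 on all 6 arrays, so the deposited values had been scaled array by array to a common target, and no further scaling was applied to them. Such scaling sets the average of each array to one level, so a change shared by most transcripts cannot be seen. MAS5 signals of dim probe sets vary widely on the log scale, which inflates their fold changes. Detection calls were not used here, and none of the 328050 values was at or below 0.

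The 54675 probe sets included 62 Affymetrix control probe sets, which were left out of the tests. Genes were named through the platform annotation, in which 41091 probe sets carried 1 gene symbol, 1801 several and 11721 none listed. Of those with 1 symbol, 41037 were found in the RefSeq gene table (assembly GRCh38.p14) through their Entrez identifiers, and 0 symbols needed an update. Probe sets with several symbols or none were tested but not named, and 848 of the called probe sets had no single symbol. No genomic coordinates are given, since the array values carry no genome build.

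Signals were taken to log2. Probe sets whose mean log2 value over the 6 arrays was below the median of all probe sets (a signal of 53.7) were removed, which left 27307. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of adjusted p below 0.05. The fit had 4 residual and 6.15 prior degrees of freedom. The probe set with the highest mean log2 value over all 6 arrays among those carrying a gene's symbol alone stood for that gene. Of the 126 genes named by rule, 65 had another probe set past the filter, 49 had at least 1 other called in the same direction, and 0 had one called in the opposite direction. For AURKB, SREBF2, ATF3, PLK3, HES1, HEY1, CLDN1, COL6A1, NDUFB8 and MFAP5, other probe sets passed the filter but were not called.

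The gene lists and the rule for naming genes were fixed before the data were examined. The rule took, among called genes whose groups did not overlap, the 12 with the largest change in each direction. It always took MFAP5, ITGAV, ITGB3, PTK2, CREB1 and TNNC1, and for each list up to 4 called members with the largest change or, where none was called, the 2 with the smallest p. Members of a list that went against most of the others, where 5 or fewer, were named after their values were seen, as were DDIT4, HMOX1, MYC and the genes named under the other observations. The 31 lists held 790 different genes, of which 618 were measured past the filter. Lists with at least 5 such genes, 28 in all, were tested against the other genes with camera in limma (preset correlation 0.01) and adjusted over the 28 lists. Of the 19 lists called, 9 kept the call when the correlation was estimated for each list. Tests that use fry ask whether the genes of a list move, on balance, one way, and do not compare it with other genes. The number of list genes called is also given adjusted over the list alone.

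For a gene whose 3 signals in a group were at or below the brightest of the 27 Bacillus control probe sets on their arrays, the fold is given as a bound, a choice made after seeing the data. The bound is the mean log2 signal of the brighter group against the mean of those control values. The brightest Bacillus control had a signal of 26.4 to 55.9. RNA quality was read from the log2 ratio of the 3' to the 5' control probe sets of GAPDH and ACTB, compared with an exact permutation test.

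The fit was tested on simulated data with 50 probe sets changed at each of 4 sizes among 27307. It recovered 2% of those changed 1.25-fold, 24% at 1.5-fold, 66% at 2-fold and 92% at 4-fold, with 1 false call among 93. Far fewer probe sets were changed in this simulation than the 25.2% called in the data. The adjustment is stricter when few change, so these values do not give the recovery or the false calls of the real comparison. With no change simulated, 0 of 28 lists were called, but the simulated probe sets varied independently, so this does not test the preset correlation. On the other 9 splits of the 6 arrays into 3 and 3, where 0 probe sets were called, the test with the preset correlation called 6 to 14 lists and that with an estimated correlation 0. Each of these splits mixes control and MFAP5 arrays on both sides. Part of the difference between the groups therefore stays in the contrast and also widens the spread, so these counts do not measure chance alone.

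Alternatives fixed in advance were quantile normalization, centring on array medians, no filter or a filter at the 75% quantile of brightness, log2 of signal plus 50, eBayes without a trend or with a robust prior, array weights and the replicate number as a block. Others were each array left out in turn, an adjusted p threshold of 0.1, the mean of all probe sets of a gene, camera with an estimated correlation, fry, and 5' against middle control probe sets. Centring on the 18 hybridisation control probe sets was added after seeing the data. Figures were drawn with matplotlib 3.10.9.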

Results

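Messenger RNA was measured in OVCA432, an established human cell line from high grade serous ovarian cancer, after exposure to microfibrillar associated protein 5 (MFAP5), a secreted glycoprotein of extracellular microfibrils. The cells were kept without serum for 24 h and then received 200 ng/mL of recombinant human MFAP5, or solvent alone, in serum-free medium. RNA was taken 48 h later and hybridised to Affymetrix U133 Plus 2.0 arrays, with 3 independently prepared samples per group and 6 arrays in all. The deposited values were MAS5 signals, scaled so that the trimmed mean of each array was 500.07. Between 27209 and 36073 probe sets per array lay above the brightest of the 27 Bacillus control probe sets, whose RNA the cells do not make. Log2 signals correlated at 0.984 to 0.988 between arrays of a group and at 0.967 to 0.971 between arrays of different groups, across probe sets, which are not independent replicates. The number of arrays limits the precision of every value.

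The comparison addressed which transcripts of the cancer cells differ after exposure to MFAP5, and whether they include the route from integrin alphaV beta3 through focal adhesion kinase (FAK) and CREB to troponin C that the study linked to this protein. With MFAP5, mRNA of the integrin subunits ITGAV and ITGB3, the receptors EGFR and MET, the chemokines CXCL1 and CXCL14 and the cytokine GDF15 was higher, and mRNA of metallothioneins was lower. Genes of the unfolded protein response and ATF4, of the TGF-beta response and of hypoxia and glycolysis lay higher as lists, and G2/M genes lower. Of 27307 probe sets tested, 3679 were higher and 3209 lower with MFAP5 (limma, adjusted p below 0.05). Changes were mostly modest: the median absolute log2 fold change of the called probe sets was 0.52, and 711 probe sets rose and 172 fell by 2-fold or more. Taken as 1 probe set per gene, 1780 of 12216 genes rose and 1869 fell. The MFAP5 and control values did not overlap for 41.0% of the probe sets, against 10% that chance gives with 3 against 3 arrays. The excess of higher over lower probe sets turned over with quantile normalization (3268 higher, 3521 lower), centring on array medians (3140 and 3974) and centring on hybridisation controls, chosen after seeing the data (1920 and 2011), and the number lower was 2118 without MFAP5 replicate 2. The counts at 2-fold were 396 higher and 73 lower with 50 added to each signal, 567 and 258 with quantile normalization, and 238 and 52 among the probe sets above the 75% quantile of brightness, where 2422 were higher and 2830 lower in all.

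Both subunits of integrin alphaV beta3, a receptor for matrix proteins with an RGD motif, were about doubled at the mRNA level. ITGAV rose 2.06-fold, from a signal of 4454 ± 454 to 9193 ± 946 (mean ± SD, n = 3 arrays each; limma adjusted p = 4.13e-05). ITGB3 rose 2.15-fold, from 1160 ± 53 to 2487 ± 72 (limma adjusted p = 4.75e-06, n = 3 each), and its 5 other probe sets past the brightness filter rose as well. PTK2, which encodes FAK, rose 1.34-fold, with a log2 fold change of 0.43 ± 0.06 (SE, limma adjusted p = 0.00108). Of its 3 other probe sets past the filter 1 also rose, and the call was lost on the arrays centred on hybridisation controls (adjusted p = 0.0724). TNNC1, the calcium-binding subunit of troponin, rose 1.47-fold, from 2707 ± 236 to 3970 ± 157 (n = 3 each, limma adjusted p = 0.000628). CREB1 did not pass the test on its brightest probe set, with a signal of 1057 ± 132.8 in control and 1078 ± 74 in MFAP5 cells (n = 3 each, limma adjusted p = 0.85). Its 6 other probe sets past the filter had log2 fold changes from -0.32 to -0.09, and none was called. The cells' own MFAP5 mRNA was 1.58-fold higher by its brightest probe set (log2 fold change 0.66 ± 0.10 SE, limma adjusted p = 0.000829), while the other probe set past the filter was not called (adjusted p = 0.39).

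**Figure D1:**
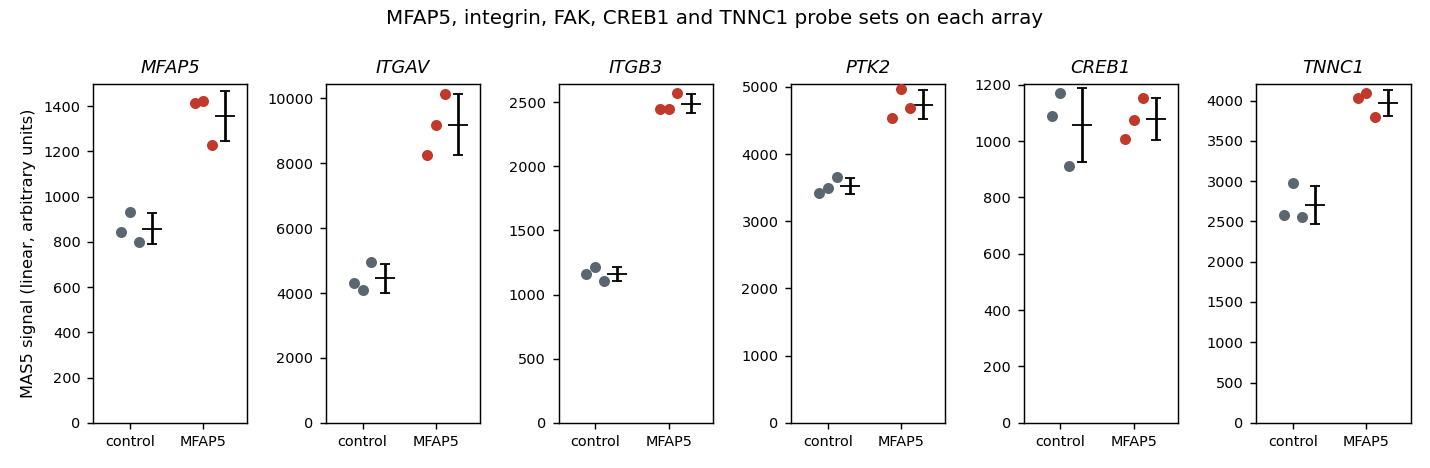
MAS5 signal (linear scale, arbitrary units) of MFAP5, ITGAV, ITGB3, PTK2, CREB1 and TNNC1 on each array, with grey points for the 3 control and red points for the 3 MFAP5 arrays and bars for mean ± SD. The 3 MFAP5 arrays lie above the 3 control arrays for every gene shown except CREB1, where the groups overlap (1057 ± 132.8 against 1078 ± 74).

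Of the 16 genes of the MFAP5 pathway list (integrins, FAK and other kinases, CREB1 and troponin genes), 9 rose, none fell and 7 were not called. Adjusted over the list alone, 10 rose. PRKCA, a protein kinase C, rose 2.04-fold (limma adjusted p = 5.14e-05) and ITGB1, the integrin beta1 subunit, 1.52-fold (adjusted p = 0.00247). The list lay higher than the other genes tested (camera adjusted p = 0.000161, and 0.0462 with an estimated correlation). The study chose this route on these samples, so neither the count nor the test is independent evidence of its direction, and the same holds for its genes wherever they stand in another list.

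CD69, an activation antigen best known from lymphocytes, and GDF15, a stress-induced cytokine of the TGF-beta family, were among the largest rises. The CD69 control signals were at or below the brightest Bacillus control on their arrays, so CD69 was at least 11.1-fold higher with MFAP5 (15.97 ± 9.003 against 438 ± 124, limma adjusted p = 3.66e-05). GDF15 rose 11.8-fold, from 93.5 ± 24.1 to 1092 ± 195 (n = 3 each, limma adjusted p = 2.63e-06). The relaxin receptor RXFP1 rose 10.7-fold, the chemokine CXCL14 10.2-fold and EBI3, a subunit of interleukins of the IL12 family, 9.59-fold. The galectin LGALS14 rose 8.26-fold, SCEL, a precursor of the cornified envelope, 8.24-fold, and RGCC, a regulator of the cell cycle, 7.24-fold (4.66-fold with the mean of all its probe sets). The chemokine CXCL1 rose 6.31-fold and the stress protein NUPR1 5.99-fold. The non-coding RNA SPRY4-IT1 (9.27-fold) and LOC613266 (8.80-fold) completed the 12 largest rises. SPRY4-IT1 and SCEL were above the brightest Bacillus control on 2 of the 3 control arrays and LOC613266 on 1, so their folds are the least certain: with 50 added to each signal they were 4.18-fold, 4.17-fold and 3.30-fold, and CD69 was 7.29-fold higher.

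Metallothioneins, small cysteine-rich proteins that bind zinc and copper, accounted for 6 of the 12 largest falls. MT1H was 18.7-fold lower with MFAP5, from 1522 ± 160 to 85.0 ± 34.0 (n = 3 each, limma adjusted p = 1.62e-06). MT1F was 13.7-fold lower, MT1HL1 11.3-fold, MT1E 11.1-fold, MT1X 6.71-fold and MT2A 4.86-fold. These 6 genes kept their calls under each scaling tried. All 10 metallothionein probe sets past the filter fell, and all 10 are of a type that can share probes between genes of this family, so the fall cannot be assigned to single members. The secretoglobin SCGB1A1 was 6.83-fold lower, and RASL11A, a small GTPase of the Ras family, 3.73-fold lower. The neuropeptide galanin (GAL) was 3.34-fold lower, from 1067 ± 120 to 321 ± 55 (limma adjusted p = 2.08e-05, n = 3 each). AOC1, a diamine oxidase, was at least 4.51-fold lower, because its MFAP5 signals were at or below the brightest Bacillus control. GNMT, a glycine methyltransferase (4.46-fold), and IGSF9 (3.51-fold) were above that control on 2 of the 3 MFAP5 arrays. With 50 added to each signal MT1H was 11.8-fold lower, SCGB1A1 4.44-fold, AOC1 2.65-fold, GNMT 2.41-fold and IGSF9 2.03-fold.

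**Figure D2:**
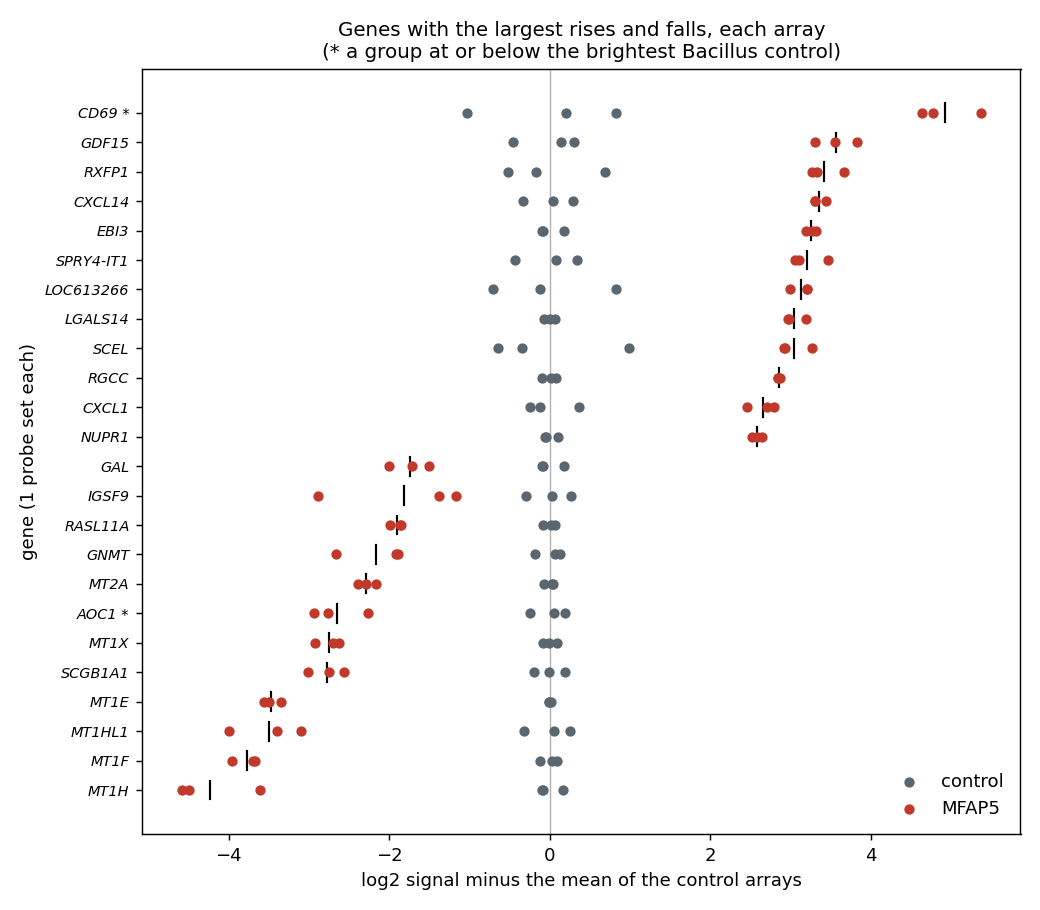
Log2 signal of each array minus the mean of the 3 control arrays for the 12 genes with the largest rises and the 12 with the largest falls, with grey points for control, red points for MFAP5 arrays, a black bar for the MFAP5 mean and an asterisk for CD69 and AOC1, where a group lay at or below the brightest Bacillus control and the drawn difference is not a measured fold. The groups do not overlap for any of these genes, and for the genes without an asterisk the MFAP5 means run from -4.23 for MT1H to 3.57 for GDF15.

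Most mitotic genes fell. Of 34 G2/M genes, 28 fell, none rose and 6 were not called, and 31 fell adjusted over the list alone. AURKB, a mitotic kinase of the chromosomal passenger complex, was 2.32-fold lower, from 2426 ± 15 to 1049 ± 76 (n = 3 each, limma adjusted p = 4.11e-06). The other AURKB probe set past the filter was not called. HMMR was 2.09-fold lower, the kinesin KIF20A 2.08-fold lower and CDC20, an activator of the anaphase promoting complex, 1.94-fold lower. The median log2 fold change of the list was -0.63, lower than the other genes tested (camera adjusted p = 1.85e-16, and 0.0196 with an estimated correlation). Of 34 G1/S genes, 14 fell, 4 rose and 16 were not called, and adjusted over the list alone 14 fell and 5 rose. ORC1, a subunit of the origin recognition complex, fell by 0.66 on the log2 scale, while CCND1 rose 1.57-fold, CCNE1 1.39-fold and CDK6 1.39-fold. The shift of this list was small (median -0.16, camera adjusted p = 0.0378, and adjusted p = 0.114 with an estimated correlation). Its call was lost without MFAP5 replicate 1 (adjusted p = 0.0777) or 2 (0.0577), and with quantile normalization (0.0735), the probe sets above the 75% quantile of brightness (0.128) or centring on hybridisation controls (0.103). The call for CDK6 was lost without control replicate 2 (adjusted p = 0.0571) or MFAP5 replicate 2 (0.066) and with centring on hybridisation controls (0.122), which also ended the call for CCNE1 (0.0681), as did a fit without an intensity trend (0.0504).

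Most genes of the unfolded protein response and ATF4 list rose. Of its 31 genes, 26 rose, 1 (DDIT4) fell and 4 were not called, and 27 rose and 1 fell adjusted over the list alone. CHAC1, which degrades glutathione, rose 2.89-fold, from 196 ± 28 to 562 ± 33 (n = 3 each, limma adjusted p = 5.15e-05). SLC7A11, the cystine transporter, rose 2.87-fold (1.91-fold with the mean of all its probe sets), ATF3 2.43-fold and DDIT3, which encodes CHOP, 1.99-fold. The other ATF3 probe set past the filter was not called. The list had a median log2 fold change of 0.45 (camera adjusted p = 6.75e-11, and 0.0196 with an estimated correlation). Of 28 genes of hypoxia and glycolysis, 16 rose and none fell, and 20 rose adjusted over the list alone. The peptide hormone ADM rose 3.21-fold, NDRG1 2.82-fold, the enolase ENO2 2.54-fold and PFKFB4 2.25-fold (list median 0.28, camera adjusted p = 3.2e-07, and 0.0474 with an estimated correlation).

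The NRF2 and oxidative stress list fell, with 14 of 22 genes lower, 2 higher and 6 not called. Adjusted over the list alone, 17 fell and 2 rose. The list was lower than the other genes tested (camera adjusted p = 3.27e-07, and 0.025 with an estimated correlation). Its largest falls were those of the metallothioneins MT1H, MT1F, MT1E and MT1X, which respond to metals and hormones as well as to oxidants. The 2 genes that rose were HMOX1, which encodes heme oxygenase, and SLC7A11. Without the 6 metallothioneins, a split made after the values were seen, 8 of the 16 remaining genes fell and 2 rose (camera adjusted p = 0.00474; adjusted p = 0.0525 with an estimated correlation).

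Of the 29 genes of the CREB and immediate-early list, 18 rose, 1 (MYC) fell and 10 were not called, and 19 rose and 1 fell adjusted over the list alone. The matricellular protein CCN2 rose 3.82-fold, from 1931 ± 82 to 7396 ± 784 (n = 3 each, limma adjusted p = 4.21e-07). The phosphatase DUSP5 rose 3.14-fold, the coactivator PPARGC1A 2.89-fold and CCN1 2.55-fold (list median 0.67, camera adjusted p = 5.67e-07, and 0.025 with an estimated correlation). Of the 10 not called, NR4A2, CRTC2, SIK1, PER2 and CREM, named after their values were seen, had log2 fold changes from -0.54 to -0.05. The others not called had positive values. The list joins CREB genes with immediate-early genes such as DUSP5, which also follows the ERK kinases, so its rise does not measure CREB activity. Of 20 TGF-beta response genes, 15 rose and none fell, with the same counts adjusted over the list alone. PMEPA1 rose 2.07-fold, BHLHE40 1.96-fold and LTBP2, a latent TGF-beta binding protein, 1.91-fold, beside CCN2 (list median 0.66, camera adjusted p = 5.67e-07, and 0.025 with an estimated correlation).

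Of 25 matrix proteases and inhibitors, 14 rose, 3 (KLK6, KLK8 and CTSL) fell and 8 were not called, and 16 rose and 3 fell adjusted over the list alone. The protease inhibitor TIMP1 rose 5.14-fold, from 195 ± 16 to 1005 ± 120 (n = 3 each, limma adjusted p = 1.41e-06). The stromelysin MMP10 rose 3.45-fold, urokinase (PLAU) 2.998-fold and ADAMTS1 2.28-fold (list median 0.46, camera adjusted p = 8.66e-05, and 0.0462 with an estimated correlation). Of 19 cholesterol synthesis genes, 11 rose and none fell, and 13 rose and 1 fell adjusted over the list alone. SREBF2, the transcription factor of this pathway, rose 1.68-fold and SC5D 1.65-fold, and IDI1 rose 1.49-fold (list median 0.29, camera adjusted p = 0.000291, and 0.0462 with an estimated correlation). IDI1 was not called when all its probe sets were averaged (adjusted p = 0.152). None of the other SREBF2 probe sets past the filter was called.

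**Figure D3:**
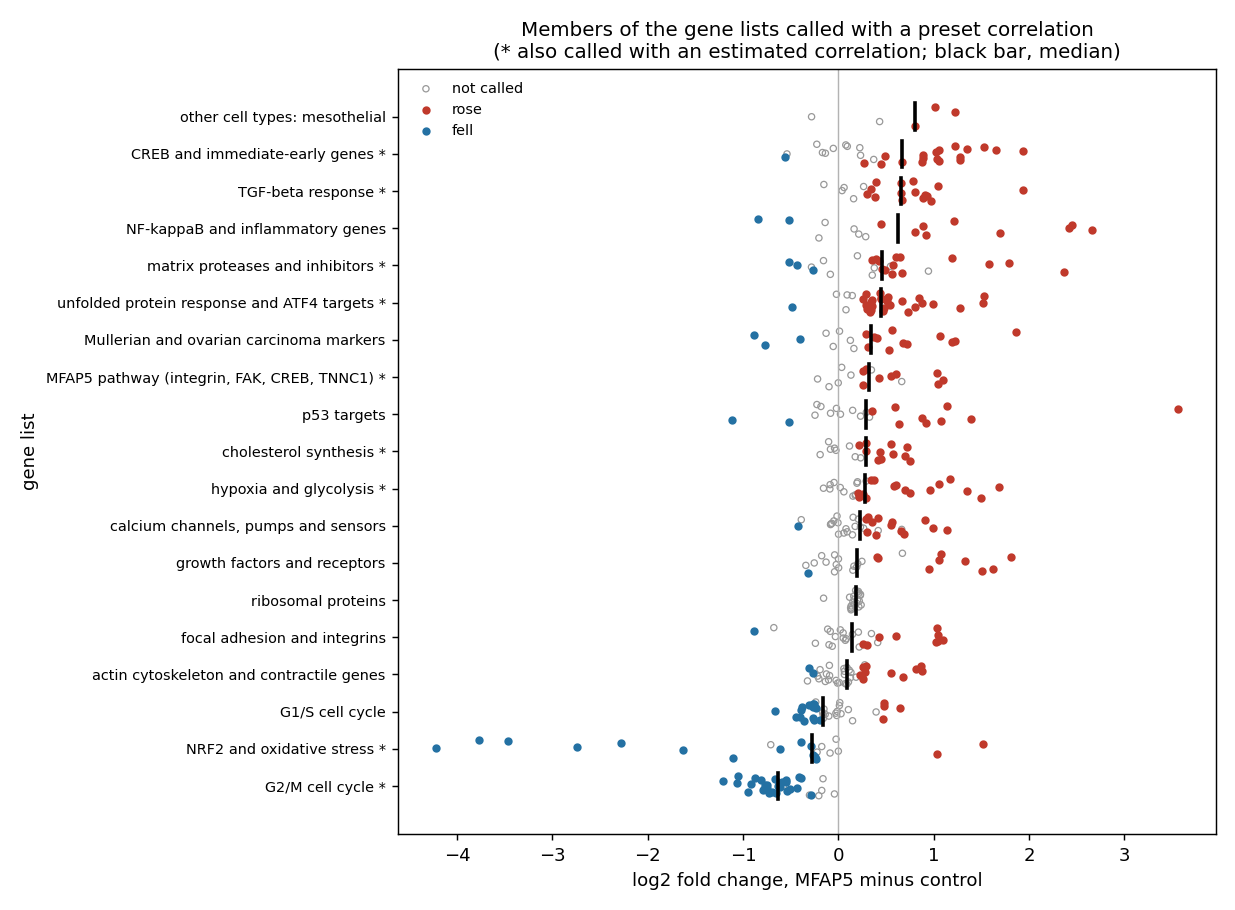
Log2 fold change (MFAP5 minus control) of each measured gene in the 19 gene lists called with the preset correlation, with red points for genes that rose, blue for genes that fell, open points for genes not called and a black bar for the list median. Medians run from -0.63 for the G2/M list to 0.80 for the mesothelial list, and an asterisk marks the 9 lists also called with an estimated correlation.

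Further lists were higher with the preset correlation alone. Of 16 NF-kappaB and inflammatory genes, 9 rose, 2 (C3 and LCN2) fell and 5 were not called, and 10 rose and 2 fell adjusted over the list alone. Beside CXCL1, the adhesion molecule ICAM1 rose 3.25-fold, from 239 ± 40 to 770 ± 34 (n = 3 each, limma adjusted p = 1.89e-05). TNF rose 5.46-fold and IL6 5.34-fold, each with only 1 of 3 control arrays above the brightest Bacillus control, and 3.06-fold and 2.73-fold with 50 added to each signal. The call of this list (camera adjusted p = 0.0042) was lost with an estimated correlation (adjusted p = 0.0763 with an estimated correlation) and among the probe sets above the 75% quantile of brightness (adjusted p = 0.511). Of 25 growth factors and receptors, 9 rose, 1 (GAS6) fell and 15 were not called, and 10 rose and 2 fell adjusted over the list alone. The receptor EGFR rose 2.83-fold, from 1547 ± 76 to 4382 ± 271 (n = 3 each, limma adjusted p = 1.03e-06), MET 3.08-fold, PDGFB 3.50-fold and IGFBP3 2.51-fold (camera adjusted p = 0.00127; adjusted p = 0.0512 with an estimated correlation).

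Of 20 Mullerian and ovarian carcinoma markers, 12 rose, 3 (MUC1, WFDC2 and WT1) fell and 5 were not called, with the same counts adjusted over the list alone. MUC16, which encodes the tumour marker CA125, rose 3.63-fold, from 447 ± 22 to 1618 ± 65 (n = 3 each, limma adjusted p = 6.44e-07). MSLN, which encodes its binding partner mesothelin, rose 2.33-fold, ceruloplasmin (CP) 2.29-fold and LYPD1 2.10-fold (camera adjusted p = 0.000953; adjusted p = 0.0892 with an estimated correlation). Of 21 p53 targets, 9 rose, 2 (FAS and DDB2) fell and 10 were not called, and 10 rose and 3 fell adjusted over the list alone. GDF15, PLK3 (2.62-fold) and ZMAT3 (2.21-fold) rose, while the death receptor FAS was 2.16-fold lower (camera adjusted p = 0.011; adjusted p = 0.119 with an estimated correlation).

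Of 33 calcium channels, pumps and sensors, 13 rose, 1 (the calcium pump ATP2B1) fell and 19 were not called, and 15 rose and 2 fell adjusted over the list alone. The calcium-binding proteins S100A4 and S100A6 rose 2.20-fold and 1.87-fold, S100A10 1.61-fold and the channel TRPC1 1.98-fold (camera adjusted p = 0.00061; adjusted p = 0.155 with an estimated correlation). Of 27 focal adhesion and integrin genes, 9 rose, 1 (FERMT1) fell and 17 were not called, with the same counts adjusted over the list alone. Caveolin (CAV1) rose 2.07-fold and ITGB8 2.05-fold, beside ITGAV and ITGB3 (camera adjusted p = 0.00779; adjusted p = 0.0991 with an estimated correlation). This list shares 7 genes with the MFAP5 pathway list, of which 5 rose, so its count is not independent of the study's choice. Among the remaining 20 genes, a split made after the values were seen, 4 rose and 1 fell. The camera p of limma for these genes was 0.16, and 0.276 with an estimated correlation. Of 37 actin cytoskeleton and contractile genes, 10 rose, 2 (TPM4 and DIAPH1) fell and 25 were not called, and 11 rose and 2 fell adjusted over the list alone. CALD1 rose 1.83-fold, ezrin (EZR) 1.82-fold, MYH10 1.75-fold and TAGLN 1.599-fold (camera adjusted p = 0.0392; adjusted p = 0.114 with an estimated correlation). The calcium and actin lists share 3 and 4 genes with the pathway list, TNNC1 among them, and without these genes, a split made after the values were seen, the camera p was 0.000958 for the calcium list (0.118 with an estimated correlation) and 0.0603 for the actin list. The call of the actin list was lost without MFAP5 replicate 2 (adjusted p = 0.055), with centring on array medians (0.0703) or hybridisation controls (0.117), and with the mean of all probe sets per gene (0.289).

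None of the 21 ribosomal protein genes was called, adjusted over all probe sets or adjusted over the list alone, although the list as a whole lay higher (median 0.18, camera adjusted p = 0.0024; adjusted p = 0.511 with an estimated correlation). That call was also lost with quantile normalization (adjusted p = 0.269), and the list was not called by fry (adjusted p = 0.17). RPS9 and RPS27 had log2 fold changes of 0.18 and 0.22 (limma adjusted p = 0.0585 and 0.0604). RPS9 was called without MFAP5 replicate 1 (adjusted p = 0.0455) or with array weights (0.0175), and RPS27 without control replicate 3 (adjusted p = 0.0325).

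Markers of other cell types were few among the probe sets past the filter. Of 5 mesothelial markers, MSLN, UPK3B (2.02-fold) and LRRN4 (1.74-fold) rose and 2 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.0129; adjusted p = 0.257 with an estimated correlation). MSLN also belongs to the ovarian carcinoma list, and LRRN4 was not called without control replicate 1 (adjusted p = 0.0662) or MFAP5 replicate 1 (0.0539) or 2 (0.0585). The fibroblast (4 measured), endothelial (3) and leukocyte (2) lists were too short to test. Of the fibroblast markers S100A4 and MFAP5 rose, and none of the endothelial markers was called, with VWF at a log2 fold change of 1.197 ± 0.548 (SE, limma adjusted p = 0.141). For VWF this was 0.47 without control replicate 2 (adjusted p = 0.359), 1.72 without control replicate 3 (0.0433) and 0.54 with 50 added to each signal (0.12). Of the leukocyte markers CORO1A rose 1.46-fold (adjusted p = 0.0212), a call lost without MFAP5 replicate 1 (0.0574) or 3 (0.0726) and on the arrays centred on hybridisation controls (0.122). Counts adjusted over the list alone were the same for these 3 lists.

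The remaining 9 lists were not called. Of 9 mesenchymal genes 3 rose, the matrix glycoprotein TNC 5.68-fold, vimentin (VIM) 2.28-fold and S100A4, and COL6A1 fell by 0.48 on the log2 scale (camera adjusted p = 0.113). COL6A1 was not called without control replicate 1 or 2 or MFAP5 replicate 1 or 3 (adjusted p = 0.101 to 0.145). Of 32 epithelial genes 8 rose, among them RAB25 (2.00-fold) and the claudins CLDN3 (1.65-fold) and CLDN1 (1.54-fold), and 1 fell (camera adjusted p = 0.123). Of 26 interferon response genes 4 rose, among them ISG20 (3.06-fold) and IFITM1 (1.74-fold), and 4 fell, among them GBP1, which was 1.82-fold lower (camera adjusted p = 0.22). Of 17 Notch genes HES1 and JAG1 rose, and LFNG (2.51-fold), HEYL (2.003-fold) and HEY1 (1.51-fold) were lower (camera adjusted p = 0.739, lower, with a median of 0.03). Of 20 apoptosis regulators 5 rose, among them PMAIP1 (2.41-fold), and 3 fell, among them CASP6, which was 1.68-fold lower (camera adjusted p = 0.817, higher, with a median of -0.06).

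Of 23 autophagy and lysosome genes 10 rose, among them CTSB (1.48-fold) and NPC2 (1.37-fold), and 4 fell (camera adjusted p = 0.0506). This list was called without control replicate 1 (adjusted p = 0.0325) or 2 (0.0434) or MFAP5 replicate 3 (0.0451). Of 13 fatty acid synthesis genes 4 rose, among them ACSL1 (1.54-fold) and SCD (log2 fold change 0.32, adjusted p = 0.1 with centring on hybridisation controls), and none fell (camera adjusted p = 0.0767, and 0.0394 without MFAP5 replicate 3). Of 13 heat shock genes 3 fell, SERPINH1, BAG3 and HSPE1, and none rose (camera adjusted p = 0.178, and 0.0297 without control replicate 3). SERPINH1 was not called without control replicate 1 or 2 or MFAP5 replicate 2 or 3 (adjusted p = 0.0583 to 0.0953), nor BAG3 without control replicate 2 or 3 or MFAP5 replicate 2 (0.0517 to 0.0961). HSPE1 was not called without any 1 of the arrays other than MFAP5 replicate 3 (adjusted p = 0.0537 to 0.105). Of 29 oxidative phosphorylation genes ATP5MC1 and NDUFB8 fell, by 0.46 and 0.20 on the log2 scale, and none rose (camera adjusted p = 0.084, and 0.00375 without control replicate 3). NDUFB8 was not called without any 1 of the arrays other than control replicate 3 (adjusted p = 0.0694 to 0.117). Adjusted over the list alone, the genes that rose and fell numbered 3 and 1 for the mesenchymal list, 11 and 1 for the epithelial, 7 and 5 for the interferon and 2 and 3 for the Notch list. They numbered 6 and 4 for the apoptosis list, 11 and 5 for the autophagy, 4 and 0 for the fatty acid, 1 and 3 for the heat shock and 0 and 1 for the oxidative phosphorylation list.

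RNA quality was read from the signal ratios of control probe sets along GAPDH and ACTB. The 3' to 5' log2 ratios differed between the groups by less than the spread between arrays. For GAPDH this ratio was -0.13 ± 0.07 in control and -0.10 ± 0.03 in MFAP5 samples (mean ± SD, n = 3 each, exact two-sided permutation p = 0.5). For ACTB it was 0.30 ± 0.06 and 0.28 ± 0.06 (n = 3 each, exact two-sided permutation p = 0.6). The 5' to middle log2 ratio of GAPDH differed by more than that spread, with 0.14 ± 0.03 in control and 0.07 ± 0.04 in MFAP5 samples (n = 3 each, exact two-sided permutation p = 0.1), and that of ACTB did not (-0.19 ± 0.03 and -0.19 ± 0.07, n = 3 each, exact two-sided permutation p = 1). The smallest p that 3 against 3 arrays can give in this test is 0.1.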

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

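All tests of the ribosomal RNA probe sets below were chosen only after the result was seen. The GAPDH and ACTB ratios among them were planned as measures of RNA quality, and only their use here was chosen afterwards. The Affymetrix control probe sets stood outside the comparison, and 6 of the human ones had all 3 MFAP5 arrays above all 3 control arrays. Chance gives a separation in either direction 10% of the time, but 41.0% of the probe sets tested showed one. The separation alone therefore does not set these control probe sets apart, and several of them measure the same RNA. The probe set for Alu repeats was higher by 0.20 on the log2 scale (0.199) and the 3' probe set of GAPDH by 0.139. The 3', 5' and middle probe sets of 18S ribosomal RNA were higher by 0.488, 0.308 and 0.437, and the 5' probe set of 28S ribosomal RNA by 0.459.

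These 4 of the 6 ribosomal RNA probe sets rose by a mean of 0.423 on the log2 scale, while the middle and 3' probe sets of 28S ribosomal RNA (0.146 and 0.088) overlapped between the groups. Array scaling is argued against as the whole source, since the median of 348 probe sets of the same brightness changed by 0.050 ± 0.048 (SE over arrays), below the bound of 0.211 set at 50% of the rise. The 3' to 5' log2 ratios gave no sign of a difference in RNA or cRNA integrity (0.03 between the groups for GAPDH, -0.014 for ACTB). The 5' to middle ratio of GAPDH differed by -0.067 ± 0.029 (SE), also below 0.211 in size. These ratios do not exclude such a difference, since the ratio that would go with the ribosomal RNA rise is not known. Their probe sets were also bright, at mean signals of 22530 to 32740 against array maxima of 38414 to 52912. Unequal hybridisation of the arrays stays open, since the median of the 18 hybridisation controls changed by 0.059 ± 0.112 (SE over arrays), too uncertain to exclude that bound, as do the ribosomal RNA carried into the labelled material and a change in the cells after MFAP5, which were not tested.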

How the results depend on the processing

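Centring on hybridisation controls was chosen after seeing the data, and the other alternatives were planned. Of the 121 called genes among the 126 named by rule, 121 kept their direction and 103 their call under every alternative that left them in the test (the 75% filter left 87 of the 126 genes and 26 of the 28 lists), and 12 lost the call without 1 of the arrays. Centring on hybridisation controls gave 1920 probe sets higher and 2011 lower. The filter at the 75% quantile of brightness, which tests fewer probe sets, gave 2422 higher, with 238 higher and 52 lower by 2-fold or more. Adding 50 to each signal, which shrinks the folds of dim probe sets, gave 396 and 73 at 2-fold and moved the folds of 11 called genes named by rule by more than 1.5 times, as the mean of all probe sets did for 2. Leaving out 1 array in turn gave 2118 (without MFAP5 replicate 2) to 3117 probe sets lower, with fewer arrays in each fit. The number of lists higher was 7 with an estimated correlation. The number of lists lower was 5 with the mean of all probe sets per gene, and 2 to 5 without 1 array (5 without control replicate 3). CREB1, not called under any of these, changed sign with centring on medians (-0.012) or hybridisation controls (-0.023), array weights (-0.010) and the mean of all probe sets (-0.209), and ranged from -0.069 to 0.112 without 1 array. Among lists not called, oxidative phosphorylation was lower with quantile normalization (adjusted p = 0.00167), centring on medians (0.0281), no filter (0.0335), array weights (0.0237) or the mean of all probe sets (0.0401), and heat shock with the mean of all probe sets (0.0486). Autophagy was higher with quantile normalization (0.0195), no filter (0.0284), the 75% filter (0.0379), the block (0.0336) or the mean of all probe sets (0.00183), and fatty acid synthesis with no filter (0.0473) or the block (0.0484). The mesenchymal list was higher with centring on hybridisation controls (0.00204) and the epithelial list with the 75% filter (0.0464). By fry, which does not compare a list with other genes, the epithelial (0.0121), mesenchymal (0.000786), interferon (0.0121), fatty acid (0.0127) and autophagy lists (0.0266) were higher. Without 1 array, fatty acid synthesis (0.0394, MFAP5 replicate 3), heat shock (0.0297) and oxidative phosphorylation (0.00375, both control replicate 3) and autophagy (0.0325, 0.0434 and 0.0451, control replicates 1 and 2 and MFAP5 replicate 3) were called. The 5' against middle log2 ratio of GAPDH differed by -0.067 ± 0.029 (SE, exact permutation p = 0.1, the smallest possible), more than the spread between arrays. Where no construction is named, the cause was not tested. With the replicate number as a block, 4214 probe sets were higher and 3774 lower. Deviations of arrays with the same number correlated at 0.0887, -0.00715 and 0.166 across probe sets. Those of arrays with different numbers correlated at -0.18 (control 3 with MFAP5 1) to 0.103 (control 2 with MFAP5 1). With so few arrays, these values do not settle whether equal numbers pair the samples. RPS27, not called, was higher with the block (adjusted p = 0.0447), and RPS9 (0.0175) and VWF (0.047) with array weights. The eBayes trend and robust prior do not enter the list tests. Signal over background limits the folds of dim genes, since 27209 to 36073 probe sets lay above the brightest Bacillus control.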

Other observations

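The tests of shared probes, of MTF1 and of p53 below were chosen only after the results were seen. The genes of this part were also chosen after their values were seen, so they show no more than their own values. Several genes of basement membrane and matrix were higher with MFAP5 beyond the lists described above. The type IV collagen chains COL4A6 and COL4A5 rose 3.87-fold and 3.13-fold (limma adjusted p = 6.7e-06 and 7.74e-06), and COL8A1 rose 3.32-fold. PXDN, a peroxidase that crosslinks type IV collagen, rose 2.97-fold, the matricellular protein SMOC2 3.21-fold and OLFML3 5.58-fold. The connexin GJB6 rose 5.79-fold, and osteopontin (SPP1), another ligand of integrin alphaV beta3, 4.93-fold (limma adjusted p = 1.83e-07).

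The zinc importer SLC39A10 rose 3.38-fold, from 3287 ± 104 to 11100 ± 352 (n = 3 each, limma adjusted p = 9.23e-08). The protease TMPRSS3 rose 3.33-fold and the hormone STC2 2.68-fold. The growth factor midkine (MDK) was 2.95-fold lower, the lysophosphatidic acid receptor LPAR3 2.87-fold and the Wnt target AXIN2 2.43-fold lower. The control received solvent alone, so the design does not separate the MFAP5 protein from anything else in its preparation.

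The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6888 probe sets and the highest of the others 0, so 1 of the 10 splits gave as many. For the gene lists the real split called 19 with the preset correlation and the highest of the others 14, so again 1 of the 10 gave as many. The others called 6 to 14 lists although they called 0 probe sets. Each of them mixes control and MFAP5 arrays on both sides, so part of the group difference stays in the contrast and widens the spread. Their counts are therefore not those of data without any change. With an estimated correlation the real split called 9 lists and each of the others 0.

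All 10 metallothionein probe sets past the filter, of 7 genes, fell. Lower activity of the metal-responsive factor MTF1 stays open, since 2 of its targets point apart: the zinc exporter SLC30A1, which it activates, was not called (log2 fold change 0.067, 95% interval -0.126 to 0.259, and -0.33 for its other probe set past the filter), while the zinc importer SLC39A10, which it represses, rose 3.38-fold. A marked fall in glucocorticoid receptor activity is argued against by 11 other targets of this receptor. Their median was 0.04 (95% bootstrap interval over the genes, not the arrays, -0.056 to 0.549). TSC22D3, FKBP5, KLF9, SGK1, PDK4 and SLC19A2 were not called, with log2 fold changes from -0.103 to 0.04. CDC42EP3, ERRFI1, CEBPD, TIPARP and IRS2 rose, by 0.418 to 0.727. Targets that also follow other signals were not taken out, so another signal could hide a fall in those that rose. With each target centred on its mean over the arrays, the per-array median of all 11 was higher with MFAP5 by 0.262 ± 0.023 (SE over arrays). This value lies between the targets not called and those that rose, so it is not the change of a typical target. A fall in receptor activity too small to move these targets is not excluded. Probes shared among the genes also stay open as a reason why so many members fell, since 0 probe sets past the filter have probes for 1 metallothionein gene alone. Below the filter, 1 probe set each of MT1M and MT1G is not of the type that can share probes. MT1M read 31.9 ± 12.85 in control and 2.16 ± 1.59 in MFAP5 samples (mean ± SD). MT1G read 22.6 ± 15.9 and 8.83 ± 4.64, with overlapping groups. Only MT1M on 1 control array exceeded the brightest Bacillus control, so these probe sets do not settle it. A change in free zinc inside the cells was not tested.

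The fall of the G2/M genes is argued against as an effect of array scaling, since the median of the 34 genes lay between -0.686 and -0.608 under quantile, median and hybridisation control scaling. Activation of p53 as its source stays open, since 13 p53 targets outside ATF4 and immediate-early signalling had a median of 0.021 (95% bootstrap interval -0.226 to 0.293) and went both ways. Cell number and cycle phase were not measured in these data.

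ETV4 (2.53-fold), ETV5 (3.18-fold), SPRY4 (3.37-fold), DUSP5 (3.14-fold) and DUSP6 (2.04-fold), genes known to follow the ERK kinases, rose, and a hypothesis was that ERK pathway output may be higher with MFAP5. In a test on 15 other genes known to follow ERK, not looked at before, the median log2 fold change was 0.287 (95% bootstrap interval 0.013 to 0.582), with 6 risen and 0 fallen. Among all genes tested, 1780 of 12216 rose. These genes lay higher than the other genes tested (camera p = 0.00538, and 0.0411 with an estimated correlation). The p values are not adjusted over the hypotheses tested in this way. The shift goes with the hypothesis on the same arrays but does not measure ERK activity.

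RARB (2.54-fold), CRABP2 (1.96-fold) and DHRS3 (1.96-fold), genes known to respond to retinoic acid, were lower, while RARG did not pass the test (log2 fold change -0.97, limma adjusted p = 0.165). A hypothesis was that retinoic acid receptor output may be lower with MFAP5. It was not borne out in 8 other targets, not looked at before, with a median of 0.067 (95% bootstrap interval -0.129 to 0.241), 2 risen and 0 fallen (camera p = 0.303, and 0.352 with an estimated correlation). The interval spans 0, so a lower output stays open.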
